A study of Mus musculus with 31 samples.

How the data were processed

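RNA was measured in mouse cells of the strain 129/OG2. Cells under reprogramming by OKSM (the factors Pou5f1, also called Oct4, Klf4, Sox2 and Myc) had been infected with a Flag virus, taken here as the control, or a Tet1CD virus, kept with DMSO (taken as the vehicle), vitamin C (Vc) or DKG, and collected at day 3 or day 8. Fibroblasts (MEF) and embryonic stem cells (ESC) were measured beside them. The labels do not say what the construct Tet1CD contains, and that the reprogramming cells came from MEF like those measured is assumed. The abbreviation DKG is not spelled out in the labels and no doses are given, so it is used here as written. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with a TruSeq RNA kit. Per the submitters' processing notes, Bowtie and RSEM were used with the mm10 genome, and their versions, read trimming and the annotation release are not given in the sources used here. Per the file headers, the deposited files are RSEM gene tables, in which the authors gave an expected count, a TPM and an FPKM per gene. RSEM shares reads that match several genes among them by its model, so the counts of genes with near-identical copies are estimates. The kit does not mark strand by its name and no counting strand is stated, so reads of overlapping or antisense genes cannot be told apart. Reads of introduced Pou5f1, Klf4, Sox2, Myc or Tet1 sequences cannot be told from those of the endogenous genes.

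The deposited expected counts were rounded to whole numbers for every test. They sum to between 3953297 and 6818060 per library. The deposited TPM served only in 1 alternative and the deposited FPKM was not used. Of 29267 Ensembl gene identifiers in the files, 28756 matched GENCODE mouse release 21 (mm10), from which symbols, chromosomes, starts and ends were taken (1-based). The other 511 held at most 0.392% of the counts of a library. At these totals, 3 counts (the upper 95% limit that a count of 0 allows) correspond to less than 1 CPM (counts scaled to one library total) in each library, and such limits cover counting error only, since reads carry no molecular identifiers.

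There were 31 libraries. The 28 libraries of the 14 groups with 2 libraries each (MEF, ESC and the 12 combinations of virus, medium and day) entered 1 fit. MEF kept with DMSO, Vc or DKG are of day 3, have 1 library each and are given as values. The title and the treatment field of the last of these name different compounds (2DG and DKG), so its identity is uncertain. Replicates carry the numbers 0824 and 0826, which the labels do not explain. The ESC libraries are called 0822 (passage 17) and 0819 (passage 19) after their titles. Their deposited files carry these numbers the other way round, so which library is of which passage is uncertain. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

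Levels are CPM with TMM-scaled library sizes, given as mean ± SD over the 2 libraries of a group (n = 2 throughout). The main test was edgeR's quasi-likelihood test (glmQLFit and glmQLFTest; edgeR 4.0.16, limma 3.58.1, R 4.3.3), two-sided, on 14914 genes that passed filterByExpr, with 1 mean per group, TMM normalization, no replicate term and Benjamini-Hochberg adjustment within each comparison. A gene was called at an adjusted p under 0.05. Without any effect, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. Where the count given is lower, the test was conservative, and 0 calls there do not show that nothing changed. Every adjusted p of a gene in the text comes from this test unless a block is named. Log2 fold changes are given ± SE, which was taken as the size of the fold change over the square root of F. No fold is given against a group with 0 counts in both libraries. Tests of interaction asked whether the effect of Tet1CD over Flag differed between a compound and DMSO. All 25 contrasts, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined.

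Whether equal numbers pair libraries was examined before calls were compared, by correlating the differences between the libraries 0824 and 0826 of each group across genes. Between groups of day 3 the correlations lay between 0.357 and 0.504 (15 pairs of groups), and between groups of day 8 between 0.343 and 0.689 (15 pairs). Across days they lay between -0.009 and 0.178 (36 pairs), and between MEF and the other groups between -0.01 and 0.306 (12 pairs). The numbers therefore pair libraries more strongly within a day than across days. The alternative planned beforehand used the number as 1 block over the 26 MEF and reprogramming libraries. A block within each day, called the within-day block below, was added after seeing the data, because the correlations were highest between libraries of 1 day. The common dispersion was 0.0817 in the main fit of 28 libraries. Over the 26 libraries without ESC and 14368 genes it was 0.0312 with the planned block and 0.0092 with the within-day block. No fit without a block was made on those 26 libraries, so the fall from 0.0817 cannot be laid to the blocks alone. The within-day block was not used for contrasts between days (day 3 against MEF and day 8 against day 3), since a term for each day takes up the spread between replicates against which these have to be tested. Counts with both blocks are given beside the main count wherever they move it by more than 1.5 times, and genes called with the within-day block alone are named as such.

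On simulated counts for the contrast of Vc against DMSO in Tet1CD cells at day 3, with 50 genes changed at each fold among 14222 genes, the main test recovered 19 of 50 genes changed 2-fold and 39 of 50 changed 4-fold with 0 false calls. The within-day block recovered 39 and 49 with 7 false calls in all, and DESeq2, over 14368 genes, 26 and 44 with 1 false call. The counts were simulated from the within-day block fit, with its replicate terms for each day and its dispersions. Its higher recovery was therefore built in and does not show that it suits the real libraries better.

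The 26 gene lists were reprogramming factors, pluripotency, fibroblast and mesenchymal, epithelial, DNA methylation machinery, methylation-silenced germline genes, histone demethylases, hypoxia and HIF targets, glycolysis, collagen modification, integrated and ER stress, p53 targets and senescence, cell cycle, oxidative stress and Nrf2 targets, cholesterol synthesis, interferon response, imprinted genes and two-cell-like genes, with markers of extraembryonic endoderm, trophoblast, mesoderm and primitive streak, neural cells, keratinocytes and stratified epithelium, macrophages and blood, endothelium, and skeletal and smooth muscle. Each list was tested against the other genes with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone.

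Genes were named by a fixed rule. It took Tet1, Tet2, Tet3, Pou5f1, Sox2, Klf4, Myc and Nanog; the 8 genes with the largest rise and the 8 with the largest fall among called genes with at least 5 CPM in the higher group and no overlap between libraries, without predicted genes; and from each list described the 4 called members with the largest change, or the 2 most abundant where none was called. The same rule was applied to calls of the within-day block. Genes outside it are said to be so. In 1 contrast, 1 gene that the rule takes and the list it belongs to are not reported here.

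Each library was placed on an axis from the MEF mean (0%) to the ESC mean (100%) by projecting its log2 CPM (prior count 2) on the difference between these means over 14914 genes. Groups were compared by exact two-sided permutation tests within strata. The alternatives fixed beforehand were DESeq2 1.42.0 (Wald test), RLE size factors, no filter on low counts, a fit of the compared groups only, the replicate block, each library left out in turn, an estimated list correlation, and for the axis another prior count, other gene sets, TPM, and exchange within pairs. Added after seeing the data were the within-day block, the same without the library Tet1CD Vc day 8 0824, which held macrophage transcripts, the list tests with no block without that library, and an axis that ends at the ESC library 0819. Tables and figures were made with Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.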

Results

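Gene expression was measured by RNA-seq in 31 libraries of mouse cells, of which 28 fell in 14 groups of 2. Total counts are given in the order of the libraries 0824 and 0826. Untreated fibroblasts (MEF) had 5552348 and 5879637. At day 3, Flag cells had 5816953 and 5350808 with DMSO, 5020466 and 4688534 with Vc, and 4750352 and 5040451 with DKG. Tet1CD cells of that day had 4206368 and 4776727 with DMSO, 5102771 and 4233404 with Vc, and 4417871 and 4872533 with DKG. At day 8, Flag cells had 6673669 and 4056235 with DMSO, 4877890 and 4211611 with Vc, and 4941323 and 3953297 with DKG. Tet1CD cells of that day had 6818060 and 3970343 with DMSO, 5357842 and 5408820 with Vc, and 6263497 and 5668541 with DKG. Embryonic stem cells (ESC) had 5114254 in the library 0822 and 5392286 in 0819. The single libraries of MEF with DMSO, Vc and DKG had 6092772, 4367018 and 4175233.

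Tet1 (ENSMUSG00000047146; chromosome 10, 62804570 to 62908996 in mm10), which encodes an enzyme that oxidises 5-methylcytosine, stood at 7.719 ± 0.1809 CPM in MEF and 386.1 ± 45.95 CPM in ESC (mean ± SD, n = 2 for every group of the comparisons). The 6 Flag groups lay between 6.144 and 18.86 CPM and the 6 Tet1CD groups between 212.6 and 611.6 CPM. Tet1 was higher with Tet1CD than with Flag in each medium and on each day, by a log2 fold change of 6.20 ± 0.66 at day 3 with DMSO and 3.48 ± 0.58 at day 8 with Vc (adjusted p = 0.000372 and 0.00767). Pou5f1 (chromosome 17, 35506018 to 35510772), an OKSM factor, lay between 975.3 and 1881 CPM in the 12 reprogramming groups, against 3.364 ± 1.458 in MEF and 710.0 ± 32.98 in ESC. Sox2 lay between 511.7 and 935.6 CPM in these groups, Klf4 between 806.8 and 1941 CPM, and Myc between 888.2 and 1738 CPM. Nanog (chromosome 6, 122707489 to 122714633), a pluripotency gene outside OKSM, lay between 1.267 and 29.86 CPM there, against 557.9 ± 73.96 in ESC.

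The contrast of ESC with MEF gave the span that reprogramming has to cover. Nanog rose from 0.6055 ± 0.5563 CPM in MEF to 557.9 ± 73.96 CPM in ESC (log2 fold change 9.78 ± 1.44, adjusted p = 3.82e-05). Pou5f1 rose from 3.364 ± 1.458 to 710.0 ± 32.98 CPM (7.71 ± 0.64, adjusted p = 1.1e-07). Dppa5a, Fbxo15 and Zfp42, markers of pluripotent cells, stood at 1104 ± 524.5, 216.2 and 192 ± 65.07 CPM in ESC and at 0 counts in both MEF libraries. Of the pluripotency list, 33 of 36 genes rose and none fell (33 and 0 adjusted over the list alone). Camera gave adjusted p = 3.74e-17 for the list, and adjusted p = 0.115 with an estimated correlation. Cell cycle genes also rose, 24 of 25 (25 adjusted over the list alone; adjusted p = 2.01e-19, and 0.00606 with an estimated correlation), among them the replication licensing genes Mcm2, from 65.59 ± 11.48 to 444.4 ± 38.48 CPM, and Mcm3, from 63.03 ± 6.064 to 432.6 ± 39.67 CPM. Tet2 rose from 25.92 ± 5.16 to 176 ± 64.06 CPM (2.77 ± 0.61, adjusted p = 0.00128), while Tet3 fell from 69.31 ± 6.235 to 14.77 ± 7.08 CPM (-2.22 ± 0.25, adjusted p = 2.56e-06). Lox, the enzyme that crosslinks collagen, fell from 4051 ± 400.8 to 522.8 ± 725.8 CPM (-2.94 ± 1.10, adjusted p = 0.0327). Its ESC libraries stood apart at 1036 CPM (0822) and 9.57 CPM (0819), and H19 at 2172 and 10.72 CPM.

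The other lists of that contrast split as follows, with counts over all genes. Of methylation-silenced germline genes 17 rose and 1 fell of 22 (the same counts adjusted over the list alone). The list had adjusted p = 6.01e-05 by camera, and adjusted p = 0.127 with an estimated correlation. Of epithelial genes 17 of 22 rose (17 adjusted over the list alone). As a list, it had adjusted p = 0.00147, and adjusted p = 0.43 with an estimated correlation. Cdh1 rose from 0.1998 to 906.8 ± 645.6 CPM. Of histone demethylases 11 rose and 1 fell of 20 (the same adjusted over the list alone). For this list camera gave adjusted p = 0.00207, and adjusted p = 0.338 with an estimated correlation. Of oxidative stress and Nrf2 targets 12 rose and 2 fell of 18 (the same adjusted over the list alone). The list test gave adjusted p = 0.00562, and adjusted p = 0.166 with an estimated correlation. Gsta4 rose from 9.142 ± 0.6318 to 292.1 ± 46.53 CPM. All 5 tested two-cell-like genes rose (5 adjusted over the list alone). Camera gave adjusted p = 0.0403 for the list, and adjusted p = 0.43 with an estimated correlation. Of fibroblast and mesenchymal genes 22 of 30 fell (27 adjusted over the list alone; adjusted p = 3.58e-07, adjusted p = 0.43 with an estimated correlation), and of collagen modification genes 19 of 20 (20 adjusted over the list alone). The list had adjusted p = 8.27e-08 by camera, and adjusted p = 0.318 with an estimated correlation.

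As lists, 17 others did not pass by camera between ESC and MEF, with adjusted p between 0.0591 and 0.933, which does not show that their members did not change. Their members that rose and fell over all genes numbered 2 and 1 of 4 reprogramming factors, 8 and 4 of 18 for DNA methylation machinery, 2 and 7 of 25 hypoxia and HIF targets, 8 and 0 of 17 for glycolysis, and 1 and 11 of 23 for integrated and ER stress. They numbered 2 and 7 of 21 p53 targets, 2 and 3 of 21 for cholesterol synthesis, 1 and 5 of 20 interferon response genes, and 4 and 9 of 24 imprinted genes. Among markers of other cells they numbered 2 and 7 of 13 for extraembryonic endoderm, 4 and 1 of 7 for trophoblast, 1 and 1 of 3 for mesoderm, 2 and 3 of 11 for neural cells, 1 and 1 of 17 for keratinocytes, 0 and 9 of 11 for macrophages, 6 and 0 of 10 for endothelium and 1 and 6 of 9 for muscle. Adjusted over the list alone, these counts changed to 7 and 0 for glycolysis, 1 and 7 for p53 targets, 2 and 2 for cholesterol synthesis, 1 and 4 for interferon and 6 and 1 for endothelium. For hypoxia and neural genes the list median was above 0 (0.102 and 0.526) while the test pointed down. In total 3991 genes were higher and 3828 lower in ESC (edgeR).

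Flag cells with DMSO at day 3 were set against untreated MEF of day 0. These groups differ by OKSM, the Flag virus, DMSO and time in culture, so the changes cannot be laid to OKSM alone. Pou5f1 rose from 3.364 ± 1.458 to 1372 ± 594.4 CPM (log2 fold change 8.65 ± 0.66, adjusted p = 1.57e-07), and Sox2, Klf4 and Myc rose too, so that 4 of 4 reprogramming factors did (4 adjusted over the list alone). As a list, it had adjusted p = 2.87e-08, and adjusted p = 0.0583 with an estimated correlation. Fibroblast markers fell: Thy1 from 756.7 ± 224 to 45.95 ± 5.851 CPM (-4.04 ± 1.10, adjusted p = 0.0109) and Postn, a matrix protein, from 1334 ± 17.4 to 71.33 ± 22.12 CPM (-4.23 ± 1.26, adjusted p = 0.0181). Of 30 fibroblast genes 12 fell (16 adjusted over the list alone; adjusted p = 8.2e-06, adjusted p = 0.499 with an estimated correlation). Collagen modification fell in 13 of 20 genes (18 adjusted over the list alone; adjusted p = 1.11e-08, adjusted p = 0.293 with an estimated correlation), including Loxl2, from 1360 ± 80.06 to 107.3 ± 20.09 CPM. The imprinted genes H19 and Igf2 fell from 5449 ± 2611 to 187.5 ± 36.05 CPM and from 4924 ± 1814 to 124.9 ± 100 CPM, and of 24 imprinted genes 11 fell and 2 rose (14 and 2 adjusted over the list alone). For this list camera gave adjusted p = 0.000143, and adjusted p = 0.293 with an estimated correlation.

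Cell cycle genes rose at day 3, 22 of 25 (22 adjusted over the list alone; adjusted p = 9.42e-14, and 0.0366 with an estimated correlation), with Mcm7 going from 66.69 ± 8.237 to 223.3 ± 22.54 CPM. Of 23 integrated and ER stress genes 12 fell (13 adjusted over the list alone). The list test gave adjusted p = 8.2e-06, and adjusted p = 0.0583 with an estimated correlation. Trib3 fell from 40.61 ± 6.139 to 1.939 ± 0.9528 CPM (-4.37 ± 0.64, adjusted p = 0.00012). Of 20 interferon genes 10 fell (12 adjusted over the list alone). Camera gave adjusted p = 3.72e-05 for the list, and adjusted p = 0.356 with an estimated correlation. All 11 macrophage and blood markers fell (11 adjusted over the list alone). The list had adjusted p = 5e-05 by camera, and adjusted p = 0.331 with an estimated correlation. Lyz2 fell from 1528 and 312 CPM in the MEF libraries to 4.331 ± 1.266 CPM. Of the pluripotency list 8 of 36 genes rose and 3 fell (10 and 4 adjusted over the list alone), and the list did not pass by camera (adjusted p = 0.4). In all, 2214 genes rose and 2070 fell (edgeR), against 3253 and 3346 with the replicate block. The total of 4284 became 2047 without the MEF library 0824 and 1777 without the Flag DMSO library 0824.

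Between day 3 and day 8, Flag cells with DMSO gained epithelial transcripts. Epcam, an epithelial adhesion molecule, rose from 3.036 ± 1.481 to 40.43 ± 14.05 CPM (log2 fold change 3.73 ± 0.86, adjusted p = 0.0443) and Lamb3, a laminin chain of epithelial basement membrane, from 3.226 ± 0.9817 to 50.04 ± 2.885 CPM (3.95 ± 0.64, adjusted p = 0.00509). Krt6a and Sprr1a, genes of stratified epithelium, rose from 4.555 ± 0.2061 to 116.2 ± 82.31 CPM and from 0.5891 ± 0.3217 to 19.04 ± 10.31 CPM. Of 22 epithelial genes 1 passed over all genes (11 adjusted over the list alone; adjusted p = 2.11e-14, adjusted p = 0.143 with an estimated correlation). Of 17 keratinocyte genes 3 rose (10 adjusted over the list alone; adjusted p = 1.02e-12, adjusted p = 0.1 with an estimated correlation). Proliferation genes fell: Mki67 from 551.4 ± 26.17 to 263 ± 49.45 CPM (-1.06 ± 0.15, adjusted p = 0.00252) and Ccna2 from 186.4 ± 17.89 to 78.56 ± 6.455 CPM (-1.24 ± 0.19, adjusted p = 0.00373), with 11 of 25 cell cycle genes (23 adjusted over the list alone). Camera gave adjusted p = 6.61e-37 for the list, and 0.000533 with an estimated correlation.

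Pluripotency genes as a list were higher at day 8 than at day 3 (adjusted p = 0.000528; adjusted p = 0.685 with an estimated correlation), with none of 36 passing over all genes (3 adjusted over the list alone). Nanog stood at 2.184 ± 1.299 CPM at day 3 and 7.616 ± 5.821 CPM at day 8. Slc7a11, a cystine transporter, rose from 8.105 ± 1.068 to 32.55 ± 13.86 CPM (2.02 ± 0.31, adjusted p = 0.00373), and Akr1c18 fell from 217.6 ± 48.65 to 21.93 ± 12.28 CPM (-3.28 ± 0.42, adjusted p = 0.00144). In all, 68 genes rose and 94 fell (edgeR), against 546 and 411 with the replicate block. The total of 162 became 36 and 9 without the day 3 libraries 0824 and 0826, and 71 and 18 without those of day 8.

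At day 3, vitamin C moved few genes past the threshold in Flag cells. With the within-day block, Mdk, a growth factor, rose from 0.9332 ± 0.297 to 9.362 ± 5 CPM (log2 fold change 3.30 ± 0.41, adjusted p = 0.000598), and L1td1, a gene of pluripotent cells, from 48 ± 30.04 to 118.4 ± 68.02 CPM (1.31 ± 0.13, adjusted p = 0.000113). Lox fell from 281.8 ± 146.6 to 140.5 ± 90.86 CPM (-1.05 ± 0.13, adjusted p = 0.000598) and Postn from 71.33 ± 22.12 to 35.34 ± 18.59 CPM (-1.04 ± 0.22, adjusted p = 0.0263). With that block, 6 of 30 fibroblast genes fell (9 adjusted over the list alone; adjusted p = 1.02e-10, adjusted p = 0.262 with an estimated correlation), and 3 of 34 pluripotency genes rose (4 rose and 1 fell adjusted over the list alone). As a list, it had adjusted p = 3.19e-05, and adjusted p = 0.262 with an estimated correlation. The test with no block called 0 genes (edgeR; 200 at an unadjusted p under 0.05; 1 by DESeq2), the replicate block 0 (595 unadjusted), and the within-day block 58 up and 59 down.

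At day 8, vitamin C raised pluripotency genes in Flag cells. Gdf3, a growth factor of pluripotent cells, rose from 0.8042 ± 0.0767 to 20.12 ± 11.86 CPM (log2 fold change 4.61 ± 0.46, adjusted p = 2.14e-05 with the within-day block and 0.00703 with the replicate block). Lin28a stood at 8.762 ± 11.04 against 0.1431 ± 0.2023 CPM (5.51 ± 0.81, adjusted p = 0.00224 with the within-day block). Nanog stood at 29.14 ± 29.35 against 7.616 ± 5.821 CPM (1.84 ± 0.39, adjusted p = 0.0211 with that block), so the level differed widely between libraries. Of the pluripotency list 0 of 36 genes passed with no block (8 rose adjusted over the list alone). The list had adjusted p = 1.36e-21 by camera, and 0.0449 with an estimated correlation. With the within-day block 16 of 34 rose (21 adjusted over the list alone; adjusted p = 0.0153 with an estimated correlation). Among DNA methylation genes Dnmt3b, a de novo methyltransferase, rose from 7.703 ± 2.055 to 32.86 ± 29.54 CPM (2.03 ± 0.35, adjusted p = 0.00457), with 4 of 18 genes of that list (6 adjusted over the list alone). The list test gave adjusted p = 0.00044, and adjusted p = 0.142 with an estimated correlation.

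Top2a, a topoisomerase, rose with Vc in these cells from 201.7 ± 15.68 to 264.5 ± 0.09897 CPM (0.40 ± 0.08, adjusted p = 0.0147 with the within-day block). It stood as high with DKG, so its rise is not particular to Vc. With that block 3 of 25 cell cycle genes rose (10 adjusted over the list alone; adjusted p = 1.23e-10 by camera, adjusted p = 0.142 with an estimated correlation). So did 3 of 20 interferon genes (7 adjusted over the list alone; adjusted p = 3.18e-09 by camera, adjusted p = 0.142 with an estimated correlation). P4ha1, a collagen prolyl hydroxylase, fell from 117.5 ± 17.66 to 74.96 ± 3.038 CPM (-0.64 ± 0.14, adjusted p = 0.0191). Nat8l fell from 325.6 ± 19.99 to 140 ± 45.26 CPM (-1.22 ± 0.15, adjusted p = 0.000306). The test with no block called 0 genes (edgeR; 371 at an unadjusted p under 0.05; 7 up and 1 down by DESeq2), the replicate block 13 up and 2 down, and the within-day block 182 up and 72 down. Of these, 113 of the 182 raised genes (62.1%) and 3 of the 72 lowered genes (4.17%) were higher in ESC than in MEF, against 24.6% of all genes tested.

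Vitamin C in Tet1CD cells raised a small set of genes by large factors at day 3. Slc38a6, an amino acid transporter of the SLC38 family (ENSMUSG00000044712; chromosome 12, 73286779 to 73354049), rose from 219.4 ± 42.46 to 4929 ± 1915 CPM (log2 fold change 4.49 ± 0.41, adjusted p = 5.54e-06). Noct, a circadian deadenylase-like protein (ENSMUSG00000023087; chromosome 3, 51224447 to 51251644), rose from 226.9 ± 21.43 to 3863 ± 1445 CPM (4.09 ± 0.33, adjusted p = 1.57e-06). Wdr31 (ENSMUSG00000028391; chromosome 4, 62448653 to 62470896) rose from 18.97 ± 5.446 to 466 ± 165.8 CPM (4.62 ± 0.41, adjusted p = 3.9e-06). The transcripts of these 3 genes, and of Slco1a6, Kif24, Gm14149 and Gm13632, carry a 50-base stretch that is also present in other genes, so their counts are uncertain. The germline genes Tex19.1 and Piwil2 rose from 0.1128 ± 0.1596 to 12.74 ± 4.476 CPM (6.60 ± 1.10, adjusted p = 0.0102) and from 1.407 ± 0.2448 to 15.27 ± 4.421 CPM (3.43 ± 0.61, adjusted p = 0.0123). They were 2 of 22 genes of the germline list (6 rose and 1 fell adjusted over the list alone). As a list, it had adjusted p = 1.45e-07, and 0.0436 with an estimated correlation.

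Interferon genes rose with vitamin C in Tet1CD cells of day 3 with the within-day block, 10 of 20 (14 adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation). Among them Isg15, a ubiquitin-like interferon product, went from 3.869 ± 3.146 to 24.65 ± 20.98 CPM (2.66 ± 0.27, adjusted p = 5.01e-06) and Oasl2 from 5.635 ± 4.479 to 29.1 ± 26.62 CPM (2.32 ± 0.33, adjusted p = 0.000349). With no block 0 of 20 passed (5 adjusted over the list alone). As a list, it had adjusted p = 6.14e-16, and adjusted p = 0.0931 with an estimated correlation. Nqo1, an Nrf2 target, rose from 48.58 to 93.97 CPM with that block, among 3 of 18 oxidative stress genes (8 adjusted over the list alone; adjusted p = 0.0296 with an estimated correlation). In all, 39 genes rose and 0 fell with no block (edgeR; 409 at an unadjusted p under 0.05; 52 up and 1 down by DESeq2), against 79 and 1 with the replicate block and 314 and 57 with the within-day block. The 39 became 16 and 17 without the DMSO libraries 0824 and 0826, and 22 without the Vc library 0824.

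At day 8 the same comparison again raised Slc38a6, from 450.9 ± 17.59 to 4267 ± 117.7 CPM (log2 fold change 3.26 ± 0.39, adjusted p = 0.000251), and Noct, from 511.6 ± 44.11 to 3502 ± 71.33 CPM (2.79 ± 0.31, adjusted p = 0.000173). Rab3gap1, a subunit of a Rab3 GTPase activator (ENSMUSG00000036104; chromosome 1, 127868773 to 127943868), rose from 168.7 ± 5.2 to 1008 ± 33.69 CPM (2.60 ± 0.21, adjusted p = 4.32e-06). Of the 39 genes raised at day 3 and the 24 raised at day 8, 22 were shared, where the product of the shares gives 0.0628; both days came from different libraries. Dazl, a germ cell RNA-binding protein, stood at 7.9 ± 0.3308 CPM with Vc and at 0 counts with DMSO. Nat8l fell from 218.1 ± 2.441 to 80.16 ± 6.66 CPM (-1.43 ± 0.24, adjusted p = 0.00893). Of the germline list 1 of 22 genes passed (7 adjusted over the list alone). For this list camera gave adjusted p = 3.5e-10, and 0.0297 with an estimated correlation. Without the Vc library 0824, which held macrophage transcripts, the latter was 0.0433 with no block and 0.138 with the within-day block.

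With the within-day block, Lin28a rose in these Tet1CD cells from 4.004 ± 4.24 to 25.44 ± 17.13 CPM (2.94 ± 0.46, adjusted p = 0.00127), with 15 of 34 pluripotency genes (20 adjusted over the list alone; adjusted p = 0.0456 with an estimated correlation). Oas1a, an interferon gene, rose from 9.17 ± 3.729 to 37.67 ± 18.43 CPM, with 16 of 20 interferon genes (20 adjusted over the list alone; adjusted p = 0.0456 with an estimated correlation). Lox fell from 391.7 ± 114.2 to 185.5 ± 88.26 CPM (-1.11 ± 0.13, adjusted p = 2.91e-05). All 11 macrophage markers also rose with that block (11 adjusted over the list alone; adjusted p = 0.0456 with an estimated correlation), and they did so in the Vc library 0824, where Lyz2 stood at 277.9 CPM against 3.285 CPM in 0826. Without that library, 10 of 35 pluripotency genes rose (18 adjusted over the list alone; adjusted p = 0.0762 with an estimated correlation), 4 of 20 interferon genes rose (13 adjusted over the list alone; adjusted p = 0.0762 with an estimated correlation), and Slc38a6, Noct and Rab3gap1 stayed raised (3.45 ± 0.25, 2.74 ± 0.27 and 2.58 ± 0.18), as did Lin28a (3.79 ± 0.54).

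Vitamin C raised 24 genes and lowered 2 in Tet1CD cells of day 8 with no block (edgeR), against 119 and 28 with the replicate block, 721 and 366 with the within-day block, and 189 and 79 with the latter without the Vc library 0824. The total of 26 became 9 and 13 without the DMSO libraries 0824 and 0826, 16 without the Vc library 0824 and 186 without the Vc library 0826. With the within-day block, Flag and Tet1CD cells of day 8, which share no libraries, had 81 raised genes in common where the product of the shares gives 9.13, and 44 lowered genes where it gives 1.83. Leaving out the Vc library 0824 gave 67 raised genes (3.39 by the product) and 25 lowered genes (0.622 by the product). Of the 721 raised genes 182 (25.2%) were higher in ESC than in MEF, as were 39 of the 366 lowered (10.7%) and 24.6% of all genes tested. Without that library these were 77 of 189 (40.7%), 9 of 79 (11.4%) and 24.8%, and with no block 15 of 24 raised genes (62.5%) against 26.8%.

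DKG was compared with DMSO to ask what the other compound does, and no gene passed the threshold on either day or with either virus. In Flag cells at day 8, Top2a stood at 270.9 ± 7.977 CPM with DKG and 201.7 ± 15.68 CPM with DMSO (log2 fold change 0.42 ± 0.13, adjusted p = 1; 0.43 ± 0.08, adjusted p = 0.42 with the within-day block). Klf4 stood at 1481 ± 678.1 and 1941 ± 733.1 CPM. Mki67 stood at 308.4 ± 52.86 and 263 ± 49.45 CPM. In Tet1CD cells at day 8, Bst2, an interferon-induced membrane protein, stood at 74.64 ± 1.865 and 59.11 ± 10.38 CPM and Piwil2 at 12.45 ± 5.663 and 8.252 ± 2.545 CPM. In that contrast the interferon list was higher with DKG (adjusted p = 1.85e-05; adjusted p = 0.909 with an estimated correlation), as was the germline list (adjusted p = 0.00751; adjusted p = 0.909 with an estimated correlation), with 0 members of either passing. At day 3, Tet1CD cells had the epithelial list lower with DKG (adjusted p = 0.00076; adjusted p = 0.963 with an estimated correlation) with 0 members passing, and Cdh1 stood at 7.08 ± 4.319 and 7.859 CPM. In Flag cells at day 3, Prdx1, a peroxide-removing enzyme, stood at 647.6 ± 34.69 CPM with DKG and 599.5 ± 85.56 CPM with DMSO. The test with no block called 0 genes in each (edgeR), with 56 and 154 at an unadjusted p under 0.05 in Flag cells of day 3 and day 8 and 58 and 50 in Tet1CD cells, and DESeq2 called 0, 0, 1 and 1. With the replicate block 0 genes passed (105, 446, 108 and 117 unadjusted), and 0 with the within-day block (234, 1157, 266 and 350 unadjusted).

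Vitamin C was also set against DKG directly. In Flag cells at day 3, Lox stood at 140.5 ± 90.86 CPM with Vc and 320.8 ± 152.8 CPM with DKG (log2 fold change -1.26 ± 0.13, adjusted p = 7.92e-05 with the within-day block) and Mdk at 9.362 ± 5 and 1.898 ± 1.6 CPM (2.32 ± 0.37, adjusted p = 0.0049 with that block), and 7 of 30 fibroblast genes were lower with Vc (12 adjusted over the list alone). For this list camera gave adjusted p = 4.06e-14, and adjusted p = 0.309 with an estimated correlation. In Flag cells at day 8, Gdf3 stood at 20.12 ± 11.86 CPM with Vc and 2.101 ± 0.2677 CPM with DKG (3.26 ± 0.40, adjusted p = 0.000424 with the within-day block) and P4ha1 at 74.96 ± 3.038 and 128.3 ± 14.82 CPM (-0.78 ± 0.14, adjusted p = 0.00508). With that block 14 of 34 pluripotency genes were higher with Vc than with DKG at day 8 (25 adjusted over the list alone; adjusted p = 0.0189 with an estimated correlation). With no block, 0 genes differed on either day (edgeR; 204 and 387 at an unadjusted p under 0.05; 0 by DESeq2 at day 3 and 4 up and 1 down at day 8). The replicate block gave 0 at day 3 and 4 at day 8, and the within-day block 54 up and 81 down at day 3 and 165 up and 104 down at day 8, which became 284 up and 163 down without the Tet1CD Vc library 0824 of day 8.

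In Tet1CD cells several genes raised over DMSO were also raised over DKG, in contrasts that share the Vc libraries. At day 3, Wdr31 stood at 466 ± 165.8 CPM with Vc and 15.1 ± 0.003017 CPM with DKG (log2 fold change 4.94 ± 0.42, adjusted p = 1.77e-06). Noct stood at 3863 ± 1445 and 203.3 ± 4.259 CPM (4.24 ± 0.33, adjusted p = 1.46e-06). Tex19.1 stood at 12.74 ± 4.476 and 0.2085 CPM (5.78 ± 1.01, adjusted p = 0.0183). At day 8, Rab3gap1 stood at 1008 ± 33.69 and 249.1 ± 20.37 CPM (2.02 ± 0.20, adjusted p = 0.000158). Slc38a6 stood at 4267 ± 117.7 and 856.6 ± 204.7 CPM (2.32 ± 0.37, adjusted p = 0.00979). Nat8l stood at 80.16 ± 6.66 and 209.8 ± 1.092 CPM (-1.39 ± 0.24, adjusted p = 0.016). Interferon genes were higher with Vc than with DKG at day 3 with the within-day block, 9 of 20 (13 adjusted over the list alone). The list test gave adjusted p = 4.77e-22, and adjusted p = 0.0504 with an estimated correlation. With no block 33 genes were higher and 0 lower with Vc at day 3 (edgeR; 369 at an unadjusted p under 0.05; 49 up and 1 down by DESeq2), against 71 and 0 with the replicate block and 266 and 44 with the within-day block, and at day 8 18 higher and 1 lower, against 52 and 12 and 457 and 247, or 88 and 44 without the Vc library 0824. At day 3 the 33 became 15 and 17 without the DKG libraries 0824 and 0826, and 22 without the Vc library 0824. The 19 of day 8 became 1 without either DKG library, 6 without the Vc library 0824 and 168 without the Vc library 0826.

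Tet1CD was compared with Flag in DMSO to ask what it changes without an added compound. At day 3, Tet1 itself was the 1 gene called with no block. With the within-day block, Slc13a5, a citrate transporter, rose from 3.975 ± 0.7711 to 21.54 ± 2.69 CPM (log2 fold change 2.44 ± 0.28, adjusted p = 0.000236), Oasl2 was higher at 5.635 ± 4.479 against 1.024 CPM (2.45 ± 0.53, adjusted p = 0.0463), and Dab1, an adaptor of reelin signalling, fell from 35.95 ± 0.2072 to 17.14 ± 2.219 CPM (-1.08 ± 0.18, adjusted p = 0.00739). The interferon list was higher (adjusted p = 3.2e-11; adjusted p = 0.351 with an estimated correlation), with 1 of 20 members passing with that block (7 adjusted over the list alone). The count of 1 up and 0 down (edgeR; 187 at an unadjusted p under 0.05; 1 and 0 by DESeq2) became 5 and 1 with the replicate block, 73 and 4 with the within-day block, and 0 without the Flag library 0824.

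At day 8, 7 genes were higher with Tet1CD than with Flag in DMSO and 0 lower: Tet1, Top2a, Irgm1, Atad2, Hells, Ncapg and Ccne2. Top2a (chromosome 11, 98992943 to 99024189) went from 201.7 ± 15.68 to 400.1 ± 17.05 CPM (log2 fold change 0.97 ± 0.13, adjusted p = 0.00601), Hells, a chromatin remodeller needed for DNA methylation, from 45.64 ± 5.863 to 99.27 ± 12.43 CPM (1.10 ± 0.18, adjusted p = 0.0264), and Irgm1, an interferon-inducible GTPase, from 8.15 ± 1.626 to 40.34 ± 10.14 CPM (2.29 ± 0.34, adjusted p = 0.015). Cell cycle genes were higher as a list, with 1 of 25 passing over all genes (12 adjusted over the list alone; adjusted p = 9.89e-27, and 0.00262 with an estimated correlation) and 14 with the within-day block. Interferon genes rose with that block, 14 of 20 (17 adjusted over the list alone; adjusted p = 0.0358 with an estimated correlation), and 7 of 34 pluripotency genes (11 adjusted over the list alone; adjusted p = 0.135 with an estimated correlation). Gdf3 rose from 0.8042 ± 0.0767 to 17.08 ± 2.833 CPM. The 4 reprogramming factors fell with that block (4 adjusted over the list alone). Camera gave adjusted p = 2.8e-08 for the list, and adjusted p = 0.0869 with an estimated correlation. Klf4 fell from 1941 ± 733.1 to 1136 ± 243.7 CPM and Pou5f1 from 1881 ± 523.9 to 1255 ± 248.7 CPM. The count of 7 (edgeR; 626 at an unadjusted p under 0.05; 36 up and 1 down by DESeq2) became 59 and 3 with the replicate block and 395 and 186 with the within-day block. It became 2 and 0 without the Flag libraries 0824 and 0826, and 4 and 2 without those of Tet1CD.

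With DKG, Tet1CD and Flag cells differed at day 8 in 5 genes, all higher with Tet1CD: Tet1, Irgm1, Gpr179 and, outside the rule and named after their values were seen, Gm14149 and Gm38194. Irgm1 stood at 44.79 ± 1.755 against 9.613 ± 0.07919 CPM (log2 fold change 2.22 ± 0.34, adjusted p = 0.0172) and Gpr179 at 60.49 ± 20.45 against 2.992 CPM (4.35 ± 0.70, adjusted p = 0.0213). The interferon list was higher, with 0 of 20 passing over all genes (15 adjusted over the list alone; adjusted p = 5.53e-40, and 0.00463 with an estimated correlation) and 16 with the within-day block, as was the cell cycle list, with 0 of 25 (16 adjusted over the list alone; adjusted p = 3.03e-36, and 0.000589 with an estimated correlation) and 18 with that block. At day 3, Tet1 was the 1 gene called, and with the within-day block Glipr1 rose from 6.295 to 24.5 ± 2.933 CPM (1.96 ± 0.21, adjusted p = 0.000143). The 5 genes of day 8 (edgeR; 420 at an unadjusted p under 0.05; 34 up and 1 down by DESeq2) became 48 up and 1 down with the replicate block and 264 and 56 with the within-day block, 0 without either Flag library, and 1 and 2 without the Tet1CD libraries 0824 and 0826. The 1 gene of day 3 (168 unadjusted; 2 by DESeq2) became 4 with the replicate block, 59 up and 5 down with the within-day block, and 0 without the Flag library 0824. With DMSO and with DKG, which share no libraries, 180 genes were raised at day 8 in both with the within-day block, where the product of the shares gives 7.26. Libraries of equal number with these media lay 2.547 and 2.799 apart for Tet1CD and 5.324 and 5.569 for Flag, in units of counting noise (chi-square per degree of freedom). The 2 libraries of a medium lay 16.81 and 16.94 apart for Tet1CD and 28.66 and 21.22 for Flag (DMSO and DKG). The 2 contrasts may therefore not be independent, which the product assumes.

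With vitamin C at day 3, Tet1CD cells differed from Flag cells in 72 genes, all higher. Wdr31 stood at 466 ± 165.8 against 14.48 ± 3.121 CPM (log2 fold change 5.01 ± 0.42, adjusted p = 1.47e-06). Mmrn2, an endothelial matrix protein, stood at 27.84 ± 5.348 against 0.7006 ± 0.1862 CPM (5.28 ± 0.87, adjusted p = 0.00442). Piwil2 stood at 15.27 ± 4.421 against 1.071 ± 0.6315 CPM (3.80 ± 0.62, adjusted p = 0.00442). Ddx58, the sensor RIG-I, stood at 44.83 ± 10.87 against 13.72 ± 2.048 CPM (1.72 ± 0.37, adjusted p = 0.0466). Of 20 interferon genes 2 passed (13 adjusted over the list alone; adjusted p = 1.47e-14, adjusted p = 0.0892 with an estimated correlation), and 14 with the within-day block (16 adjusted over the list alone; adjusted p = 0.0575 with an estimated correlation). With that block 16 of 25 cell cycle genes fell (22 adjusted over the list alone). The list had adjusted p = 3.73e-09 by camera, and adjusted p = 0.133 with an estimated correlation. Top2a fell from 483.8 ± 7.763 to 361.2 ± 25.37 CPM (-0.41 ± 0.08, adjusted p = 0.00158), and 13 of 30 fibroblast genes rose (22 adjusted over the list alone). As a list, it had adjusted p = 6.38e-09, and adjusted p = 0.176 with an estimated correlation. Of 1403 genes raised with that block 173 (12.3%) were higher in ESC than in MEF, and of 929 lowered 523 (56.3%), against 24.6% of all genes tested. With no block the share turned the other way, at 34 of 72 raised genes (47.2%) against 26.8% of all genes. For Tet1CD over Flag with the within-day block, the share of raised genes at day 3 was 20.5% with DMSO and 25.4% with DKG. At day 8 the shares of raised and lowered genes were 61% and 20.4% with DMSO and 56.1% and 8.93% with DKG. With Vc they were 28.5% and 21.9%, including the library that held macrophage transcripts. The 72 (edgeR; 1128 at an unadjusted p under 0.05; 142 up and 6 down by DESeq2) became 373 up and 86 down with the replicate block and 1403 and 929 with the within-day block, 25 and 30 without the Flag libraries 0824 and 0826, and 32 without the Tet1CD library 0824.

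At day 8 with vitamin C, 35 genes were higher with Tet1CD and 0 lower. Top2a stood at 431.1 ± 2.746 against 264.5 ± 0.09897 CPM (log2 fold change 0.71 ± 0.13, adjusted p = 0.0219). Slco1a6, an organic anion transporter, stood at 22.26 ± 2.052 against 1.104 ± 0.4712 CPM (4.33 ± 0.46, adjusted p = 4.69e-05). Spp1, a secreted phosphoprotein, stood at 225.3 ± 102.6 against 32.76 ± 2.979 CPM (2.78 ± 0.28, adjusted p = 3.29e-05; 2.17 ± 0.15 with the within-day block without the Tet1CD library 0824). Cell cycle genes were higher, 1 of 25 over all genes (18 adjusted over the list alone; adjusted p = 4.06e-20, and 0.0105 with an estimated correlation), where at day 3 they fell with the within-day block. Interferon genes were higher too, with 0 of 20 passing (15 adjusted over the list alone; adjusted p = 1.11e-21, and 0.0436 with an estimated correlation) and 19 with the within-day block. Without the Tet1CD library 0824, which held macrophage transcripts, the cell cycle list had adjusted p = 0.0459 with an estimated correlation and no block, and 0.162 with the within-day block. The interferon list then had adjusted p = 0.0646 and 0.0949 with an estimated correlation. The 4 reprogramming factors fell with that block (4 adjusted over the list alone). For this list camera gave adjusted p = 2.37e-08, and adjusted p = 0.0834 with an estimated correlation. The viruses thus differed in the level of the OKSM factors with Vc too. The macrophage genes Mpeg1 and Gpnmb were also called, at 118.5 and 3.833 CPM and at 661.4 and 56.22 CPM in the Tet1CD Vc libraries 0824 and 0826. Both also stood higher with Tet1CD in the within-day block without the library 0824 (log2 fold change 4.46 ± 0.82 and 2.68 ± 0.3). The 35 (edgeR; 1132 at an unadjusted p under 0.05; 135 up and 18 down by DESeq2) became 246 up and 72 down with the replicate block, 1079 and 821 with the within-day block, and 472 and 442 with the latter without the library 0824. With no block it became 21 and 15 without the Flag libraries 0824 and 0826, and 202 without the Tet1CD library 0826.

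Whether vitamin C and Tet1CD together gave more than the sum of both on the log scale was asked by a test of interaction. At day 3, 15 genes passed, and each had a larger effect of Tet1CD with Vc than with DMSO. Slc38a6 stood at 182 ± 11.38 CPM with Vc in Flag cells and 4929 ± 1915 CPM in Tet1CD cells (interaction 4.55 ± 0.53 on the log2 scale, adjusted p = 0.000233). Noct stood at 194.3 ± 10.86 and 3863 ± 1445 CPM (4.02 ± 0.43, adjusted p = 9.91e-05). Rab3gap1 stood at 115.6 ± 4.921 and 1160 ± 404.6 CPM (3.22 ± 0.29, adjusted p = 2.22e-05). Its transcript length, weighted by abundance, moved by -28.4% and -24.9% with Vc over DMSO in Tet1CD cells (0824 and 0826). The reads of Rab3gap1 may thus come from other transcripts than with DMSO. The others were Wdr31, Slco1a6, Cep112it, Baiap2l1 and Kif24, and 7 predicted genes. At day 8, 3 genes had a larger effect and 0 a smaller one: Rab3gap1 (2.31 ± 0.28, adjusted p = 0.00147), Slco1a6 (5.15 ± 0.63, adjusted p = 0.00147) and, outside the rule and named after its values were seen, the predicted gene Gm38279 (2.81 ± 0.46, adjusted p = 0.0434). All 3 were among the 15, where the product of the shares gives 0.00302. No list passed in the test of interaction with an estimated correlation. In edgeR 253 genes of day 8 had an unadjusted p under 0.05. DESeq2 called 23 genes at day 3 and 10 at day 8, and the replicate block 25 and 5. The within-day block called 52 up and 7 down at day 3 and 14 up and 4 down at day 8. Without the Tet1CD Vc library 0826 of day 8 the 3 became 8, and without the other libraries of that test the lowest count was 2.

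Tet1CD by DKG interactions called 0 genes on either day (edgeR; 47 and 86 at an unadjusted p under 0.05; 0 and 2 by DESeq2; 0 with either block). Slc38a6 stood at 237.1 ± 6.215 CPM in Tet1CD cells with DKG at day 3 and 856.6 ± 204.7 CPM at day 8, against 219.4 ± 42.46 and 450.9 ± 17.59 CPM with DMSO. Rab3gap1 stood at 121.6 ± 0.2784 and 249.1 ± 20.37 CPM with DKG, and at 128.2 ± 1.296 and 168.7 ± 5.2 CPM with DMSO.

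**Figure D1:**
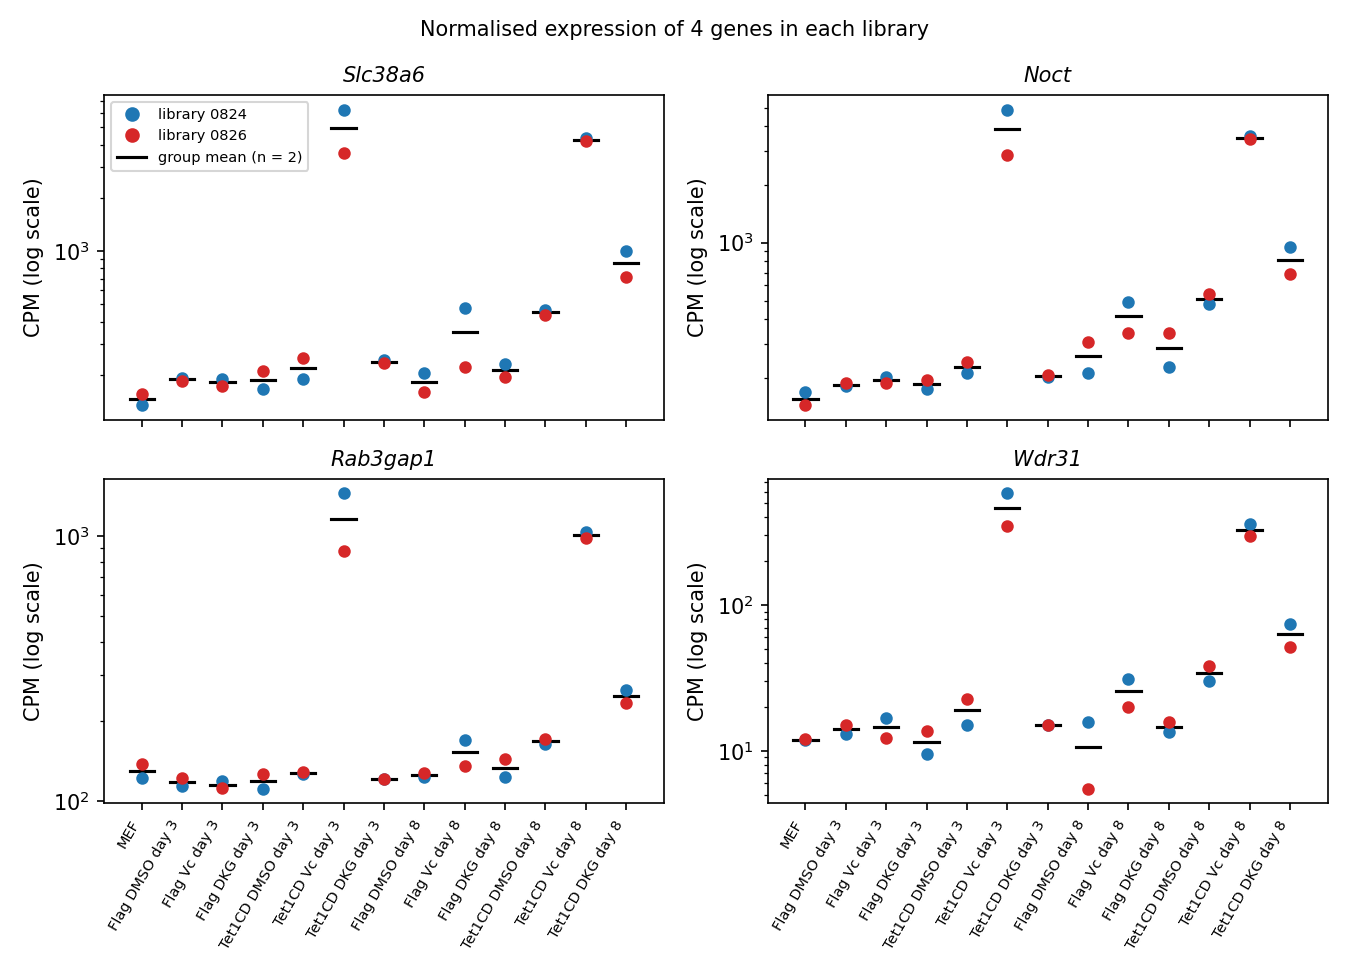
CPM (log axis) of Slc38a6, Noct, Rab3gap1 and Wdr31 in each library of MEF and the 12 reprogramming groups, with points for libraries and lines for group means. The Tet1CD libraries with Vc stand apart on both days, with a mean for Rab3gap1 of 1160 CPM at day 3 and 1008 CPM at day 8.

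**Figure D2:**
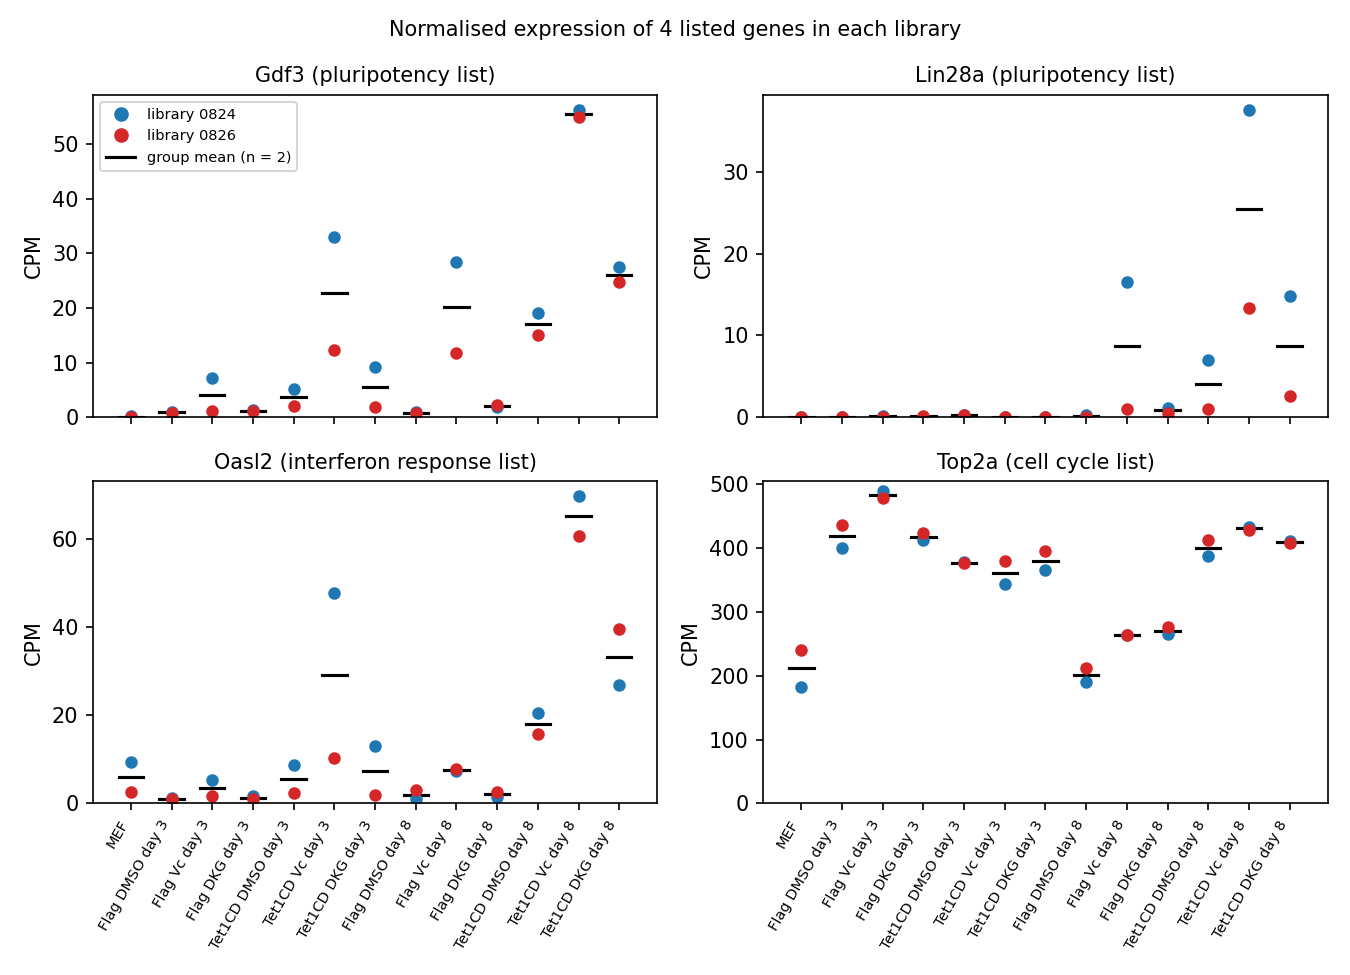
CPM (linear axis from 0) of Gdf3 and Lin28a (pluripotency), Oasl2 (interferon response) and Top2a (cell cycle) in each library of MEF and the 12 reprogramming groups, with points for libraries and lines for group means. Gdf3 at day 8 has a mean of 0.8042 CPM in Flag cells with DMSO and 20.12 CPM with Vc.

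How far each library had moved from MEF towards ESC was summarised as a position on the axis between their means. Flag cells with DMSO stood at 34.87% ± 4.42 at day 3 and 37.96% ± 7.33 at day 8, and Flag cells with Vc at 38.73% ± 6.53 and 44.18% ± 9.29. Tet1CD cells stood closer together, at 33.17% ± 2.55 and 40.48% ± 6.82 with DMSO and 33.54% ± 3.35 and 43.08% ± 5.03 with Vc, and whether the shift with Vc differs between the viruses was not tested. The ESC libraries stood at 78.59% (0822) and 121.41% (0819). Over both viruses and days, Vc stood at 39.88% ± 6.613 and DMSO at 36.62% ± 5.203, a difference of 3.261 points (exact permutation p = 0.2392, adjusted over 5 tests 0.3987, two-sided). Exchanging media within libraries of equal number gave an exact permutation p of 0.01562, with Vc higher in 7 of 8 pairs (95% interval 1.038 to 5.605 points). Without the Flag Vc libraries of day 8, 0824 and 0826 in turn, the difference was 1.618 and 4.903 points. DKG stood at 36.44% ± 5.6, a difference from DMSO of -0.1824 points (exact permutation p = 0.9136, adjusted 0.9136; interval -1.159 to 0.82). Vc exceeded DKG by 3.443 points (exact permutation p = 0.2022, adjusted 0.3987), in 8 of 8 pairs (exact permutation p within pairs 0.007812, the smallest they can give; interval 1.371 to 5.679). Tet1CD cells stood at 32.8% ± 2.541 at day 3 against 36.01% ± 4.355 for Flag cells (exact permutation p = 0.1759, adjusted 0.3987), lower in 6 of 6 pairs (exact permutation p within pairs 0.03125, the smallest they can give). At day 8 they stood at 41.57% ± 5.125 against 40.21% ± 6.753 (exact permutation p = 0.6759, adjusted 0.8449). None of the 5 tests passed after adjustment when libraries were not paired. Within pairs, adjustment over the 5 tests gave 0.03906 for Vc over DMSO and for Vc over DKG, which passed, and 0.05208 for Tet1CD at day 3, 0.3516 at day 8 and 0.6797 for DKG over DMSO, which did not. Without the Flag Vc libraries of day 8, 0824 and 0826 in turn, Vc exceeded DKG by 1.801 and 5.085 points.

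**Figure D3:**
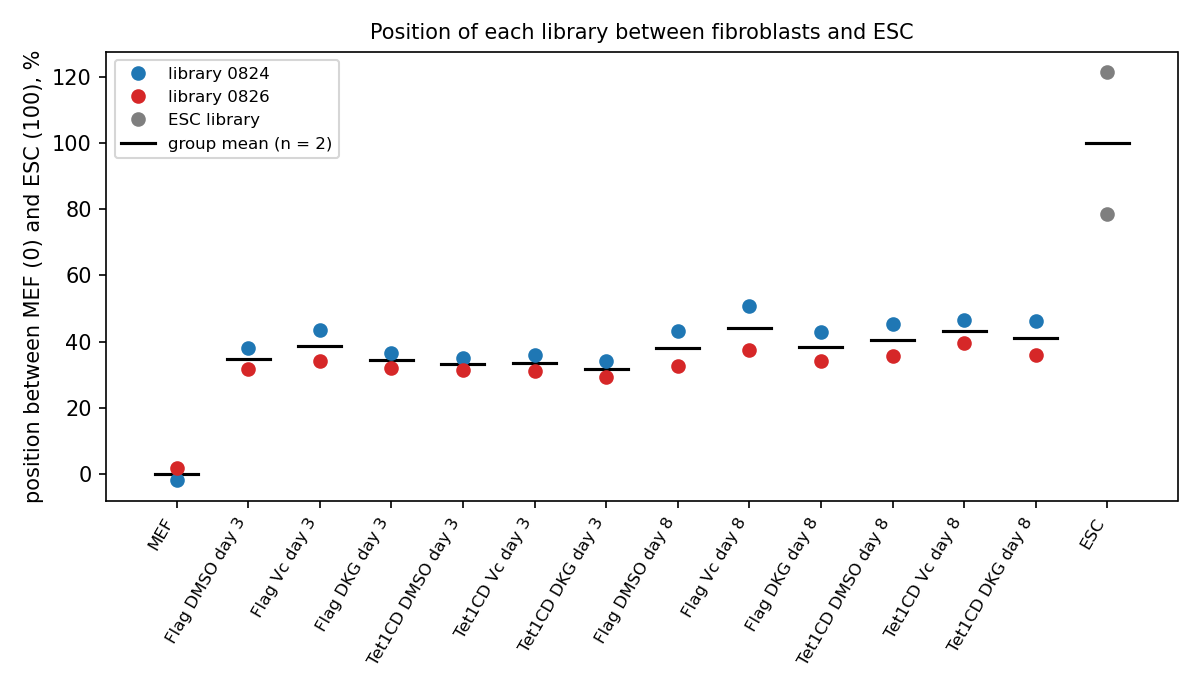
Position of each library between the MEF mean (0%) and the ESC mean (100%), in percent, by group, with points for libraries and lines for group means. The reprogramming groups have means between 31.69% and 44.18%.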

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

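The tests of explanations in this part were fixed before their results were seen, but the set of 52 genes they use was called with the within-day block, which was chosen after seeing the data.

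MEF kept with Vc, a single library that enters no comparison, had Pou5f1 at 12.74 CPM (48 counts), above the highest level in the MEF libraries without a compound or with DMSO (4.395 CPM). Sox2 stood at 6.899 CPM in the same library (26 counts), above their highest level of 2.969 CPM.

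The effect of Tet1CD over Flag differed between Vc and DMSO in 15 genes at day 3 and in 3 at day 8 by a test of interaction. Each of these genes stood highest, among the 6 group means of its day, where Tet1CD and Vc were combined. By the within-day block 52 genes had a larger effect at day 3 and 14 at day 8, with 13 in common where the product of the shares gives 0.0507, and 17 of the 52 are predicted genes. Slc38a6, Noct, Wdr31 and Rab3gap1 are among them.

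Whether a few genes took the counts was tested by leaving the 52 genes out of the library sizes. The median log2 fold change of Vc over DMSO in Tet1CD cells of day 3 was then 2.306. Their share of the counts was 2.85% and 1.853% in the Vc libraries and 0.352% and 0.4291% in those with DMSO. Shares of this size move the library sizes too little to bring the median under the limit set beforehand. The test could therefore not have come out otherwise, and it excludes nothing. Of the 52 genes 51.92% shared an exact stretch of 50 bases with another of them, against a median of 3.846% and a 95th percentile of 11.54% in 1000 random sets, so part of the set may hold reads assigned among copies of 1 sequence. Stretches found in 5 or more of the genes occurred in 12 of them, such as Wdr31, Noct and Slc38a6, and in 8 tested genes outside the set, whose median log2 fold change was 0.585 (95th percentile of random sets 0.13; 7 of 8 above 0, from Gm11127 at 4.83 and Patj at 1.23 to Prnp at -0.25). Of 29 genes with 2 or more transcripts 7 (24.14%, against a 95th percentile of 13.79% in random sets) had a weighted transcript length that moved by over 10% the same way in both replicates, so the reads could come from other transcripts than in the DMSO cells. These were Dhx16, Glipr1, Gm16001, Kif24, Noct, Rab3gap1 and Snhg14. Repeated sequences that are expressed from many places when Tet1CD and Vc meet, and that extend into these genes, are 1 hypothesis that these values leave open beside reads shared between copies, and the reference used here holds no annotation of repeats to name them.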

How the results depend on the processing

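The within-day block, the same without the Tet1CD Vc library 0824 of day 8, the list tests without that library, and the axis that ends at the ESC library 0819 were chosen after seeing the data. Counts are genes called in both directions together. RLE size factors left all 25 counts within 1.5 times of the reported ones, and 7752 of 7819 genes of ESC against MEF, 4078 of 4284 of day 3 against MEF and 144 of 162 of day 8 against day 3 stayed called in the same direction. The axis differences kept their direction and their side of the threshold with another prior count, other gene sets, TPM, RLE size factors and the ESC library 0819 as its end (Vc over DMSO 2.565 to 3.615 points). Where a count moved by more than 1.5 times it is given below, and the cause was not tested except where stated. Libraries held between 3953297 and 6818060 counts, which limits what can be said of genes near 1 CPM, such as Lin28a at 0.1431 CPM in Flag cells with DMSO at day 8.

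With only the groups of the comparison in the fit, which leaves fewer libraries to estimate the spread, ESC against MEF gave 2031 genes and Vc against DMSO in Tet1CD cells of day 8 gave 12. The count became 0 for day 8 against day 3 (edgeR; 1253 at an unadjusted p under 0.05; 359 by DESeq2) and for Vc against DKG in Tet1CD cells of day 8 (505 unadjusted; 75 by DESeq2). It also became 0 for Tet1CD against Flag with DMSO at day 8 (269 unadjusted; 37 by DESeq2), with Vc at day 8 (592; 153), with DKG at day 3 (307; 2) and at day 8 (331; 35), and for the interaction of Tet1CD with Vc at day 8 (140; 10).

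The replicate block gave 6599 genes for day 3 against MEF, 957 for day 8 against day 3, and for Vc against DMSO 15 in Flag cells of day 8 and 80 and 147 in Tet1CD cells of day 3 and day 8. For Vc against DKG it gave 4 in Flag cells of day 8 and 71 and 64 in Tet1CD cells of day 3 and day 8. For Tet1CD against Flag on these days it gave 6 and 62 with DMSO, 459 and 318 with Vc, and 4 and 49 with DKG, and 25 and 5 for the interaction with Vc. This block removes a difference between the numbers 0824 and 0826 that the groups share. Its fit also leaves out the ESC libraries, as does that of the within-day block, so the change in counts cannot be laid to the blocks alone. On the axis, exchange within pairs of equal number left the differences at -3.205 points for Tet1CD at day 3 (exact permutation p = 0.0312, lower in 6 of 6 pairs), 3.261 for Vc over DMSO (exact permutation p = 0.0156, higher in 7 of 8 pairs) and 3.443 for Vc over DKG, each now past the threshold before adjustment, and the last 2 after it (0.03906 for both). For Tet1CD the 6 pairs may not be independent, as stated above.

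The within-day block removes such a difference separately for each day and lowered the dispersion further than the replicate block did. It gave, for Vc against DMSO at day 3 and day 8, 117 and 254 genes in Flag cells and 371 and 1087 in Tet1CD cells. For Vc against DKG it gave 135 and 269 in Flag cells and 310 and 704 in Tet1CD cells. For Tet1CD against Flag it gave 77 and 581 with DMSO, 2332 and 1900 with Vc, and 64 and 320 with DKG, and 59 and 18 for the interaction with Vc. Without the Tet1CD Vc library 0824 of day 8 these became, in the same order, 166 and 380, 493 and 268, 214 and 447, 419 and 132, 116 and 889, 2681 and 914, 119 and 458, and 107 and 17. DKG against DMSO in Flag cells of day 8 and the interaction of Tet1CD with DKG at day 8 each became 1. Leaving out 1 library here also changes the genes tested and the spread of every other contrast.

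DESeq2 gave 359 genes for day 8 against day 3, for Vc against DMSO 1 and 8 in Flag cells of day 3 and day 8 and 112 in Tet1CD cells of day 8, and 1 for DKG against DMSO in Tet1CD cells of day 3 and of day 8. For Vc against DKG it gave 5 in Flag cells of day 8 and 50 and 75 in Tet1CD cells of day 3 and day 8. For Tet1CD against Flag it gave 37 with DMSO at day 8, 148 and 153 with Vc and 2 and 35 with DKG at day 3 and day 8. For the interaction with Vc it gave 23 and 10, and for that with DKG at day 8 it gave 2. With no filter on low counts, Vc against DMSO gave 3 in Flag cells and 110 in Tet1CD cells of day 8, Vc against DKG 90 in the latter, Tet1CD against Flag at day 8 132 with Vc and 21 with DKG, and the interaction with Vc at day 8 gave 8.

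With each library left out in turn, the lone library of its group is assumed to vary like the other groups. The counts then ranged from 1777 to 2930 for day 3 against MEF and from 9 to 71 for day 8 against day 3. In Tet1CD cells of day 3 and day 8 they ranged from 16 to 36 and from 9 to 186 for Vc against DMSO, and from 15 to 30 and from 1 to 168 for Vc against DKG. For Tet1CD against Flag on these days they ranged from 0 to 1 and from 0 to 4 with DMSO, from 25 to 59 and from 15 to 202 with Vc, and from 0 to 1 and from 0 to 2 with DKG, and for the interaction with Vc at day 8 from 2 to 8. The axis difference between DKG and DMSO ranged from -1.479 to 1.114 points and that between Tet1CD and Flag at day 8 from -0.833 to 3.547, so both changed sign. The others kept theirs, from -4.745 to -1.665 for Tet1CD at day 3, from 1.618 to 4.903 for Vc over DMSO and from 1.801 to 5.085 for Vc over DKG. ESC against MEF (5720 to 8866) and the interaction at day 3 (11 to 19) stayed within 1.5 times, and contrasts with 0 genes stayed at 0.

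Of 157 list calls outside ESC against MEF, in 624 tests, 16 remained with an estimated correlation and 153 with RLE size factors. Without the Tet1CD Vc library 0824 of day 8 and with no block, 152 lists were called (141 of the 157), and 14 with an estimated correlation. The replicate block called 177 lists (144 of the 157 among them) in 600 tests. The within-day block called 188 (126 of the 157) in 550 tests that leave out the contrasts between days, and 27 (24 of the 157) with an estimated correlation. Of the named genes, 1177 over all contrasts, none that was called with no block or under an alternative had opposite signs in these 2 tests. The macrophage genes Lyz2 and Ctss, which rose with the within-day block for Vc against DKG in Tet1CD cells of day 8, lost their call and changed sign (-0.33 and -0.28) without the Vc library 0824. With the replicate block 1015 kept their side of the threshold, 106 came past it and 0 lost it, and with the within-day block 457, 554 and 0, where many of the 554 were named because this block called them. With DESeq2 these were 1088, 67 and 14, with no filter 1105, 63 and 9, with only the compared groups 1019, 4 and 89, with RLE size factors 1172, 1 and 4, and over all fits without 1 library 4735, 39 and 346.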

Other observations

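The tests on macrophage genes and on the ESC libraries, and those on DKG in Tet1CD cells, were chosen after their results were seen, and the test on DKG in Flag cells was fixed before.

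Gene groups differed between the single libraries of MEF kept with a compound and of MEF kept with DMSO. In MEF kept with Vc all 20 interferon genes stood higher than in MEF kept with DMSO, with a median log2 ratio of 1.6 (percentile 100 among 10000 random lists of like mean abundance over all 31 libraries), as did 19 of 21 cholesterol genes (0.387; percentile 100). Of 23 integrated and ER stress genes 5 stood higher (-0.814; percentile 0), of 25 cell cycle genes 1 (-0.355; percentile 0.04), of 25 hypoxia genes 7 (-0.224; percentile 1.27), and of 11 neural genes 5 (-0.448; percentile 1). Oxidative stress genes stood higher in 14 of 18 (0.186; percentile 98.45) and p53 targets in 12 of 21 (0.151; percentile 98.19). Reprogramming factors stood higher in 3 of 4 (1.091; percentile 100) and imprinted genes in 16 of 24 (0.237; percentile 99.62). In the library labelled with DKG, whose title names 2DG, 15 of 17 glycolysis genes stood higher than with DMSO (0.109; percentile 99.91) and 8 of 30 fibroblast genes (-0.084; percentile 1.64). Trophoblast genes stood higher in 4 of 7 (0.481; percentile 99.42) and reprogramming factors in 1 of 4 (-0.35; percentile 0). The latter list lay at opposite ends with Vc and with DKG, but it rests in part on few counts. With DMSO, Vc and DKG, Pou5f1 had 1, 48 and 0 counts and Sox2 11, 26 and 2. Over all libraries, on which the random lists were matched, the OKSM factors are more abundant than in MEF. The percentiles of this list can therefore not be read as an effect of the medium. The lists not named here lay between the percentiles 11.04 and 93.39 with Vc and between 18.39 and 96.55 with DKG. Tet1, Tet2 and Tet3 stood at 10.29, 26.67 and 74.29 CPM with DMSO, 11.68, 17.78 and 45.38 CPM with Vc, and 7.7, 18.15 and 62.97 CPM with DKG. No test of the medium applies to 1 library each, and libraries without Vc also differed. In units of counting noise, MEF kept with DMSO lay 14.29 from MEF kept with Vc, 2.277 from MEF kept with DKG, and 17.11 and 8.844 from the untreated MEF libraries 0824 and 0826.

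Flag cells shared 29 genes raised by Vc at day 3 and at day 8 with the within-day block, which was chosen after seeing the data, where the product of the shares gives 0.735, and 24 lowered genes where it gives 0.296. At day 3, Flag and Tet1CD cells shared 19 raised genes (1.27 by the product) and 14 lowered genes (0.234 by the product). No gene was raised in one and lowered in the other of these contrasts with that block.

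The Tet1CD library with Vc of day 8 numbered 0824 held macrophage transcripts that its partner 0826 did not, with C1qb at 159.9 and 0.365 CPM, Csf1r at 207.8 and 0.9126 CPM, and Lyz2 at 277.9 and 3.285 CPM. Reads carried over from the MEF library of the same number, which holds these transcripts too, were argued against: 142 genes abundant in that MEF library and low in the cultures stood at a median of -0.08177% of their MEF level above the DMSO and DKG cultures (quartiles -2.204% and 2.17%), and the macrophage genes at 90.38%. All 11 tested macrophage and blood genes were highest in this library among the 12 of day 8, so macrophages in that culture may be a source, and macrophage RNA added later stays open too. Contrasts that use this library are given without it as well.

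The ESC libraries differed in fibroblast genes: H19 stood at 2172 CPM in 0822 and 10.72 CPM in 0819, Col1a1 at 4269 and 28.52 CPM, Lox at 1036 and 9.57 CPM, and Postn at 506.5 and 2.488 CPM. Over 162 genes abundant in MEF and under 1 CPM in 0819, the levels in 0822 were a median of 25.57% of the MEF level (quartiles 20.81% and 31.56%), a nearly even share, so fibroblast RNA in this library may account for them. Whether cells that had left the pluripotent state contributed stays open. In 0822, 32 pluripotency genes stood at a median of 83.96% of their level in 0819 (quartiles 66.11% and 123.8%). This range includes the 74.43% that such a share of departed cells would leave. Fibroblast RNA mixed in at the same share would also leave 74.43%, so these values cannot tell the 2 sources apart. The contrast of ESC with MEF and the 100% end of the axis rest on the mean of both libraries.

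A hypothesis tested on these data is that DKG moves the genes raised by Tet1CD with Vc in the same direction, though less. In Tet1CD cells of day 8 the 52 genes of the day 3 interaction had a median log2 fold change of 0.305 for DKG over DMSO (41 of 52 above 0; 95th percentile of random sets 0.04), against 1.58 for Vc. The 12 of them with a stretch found in 5 or more of the set had a median of 0.685 for DKG, and the 8 such genes outside the set 0.185. Random sets were matched on expression only, while 51.92% of the 52 genes share a stretch with another and may move together. These percentiles may therefore make the set look more unusual than it is. In Tet1CD cells of day 3 the 14 genes of the day 8 interaction had a median of 0.065, just above the 95th percentile of 0.06, with 8 of 14 above 0. In Flag cells of day 8 the 52 genes had a median of 0.055, which did not exceed the 95th percentile of 0.06. So a small effect of DKG on these genes is possible in Tet1CD cells of day 8, no single gene passed in that contrast (edgeR; 50 at an unadjusted p under 0.05; 1 by DESeq2), and the difference between the viruses was not tested for the set.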
